A study of Saccharomyces cerevisiae with 9 samples.

How the data were processed

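Chromatin of budding yeast was immunoprecipitated with an antibody against Snf5, a subunit of the SWI/SNF chromatin remodeler, and hybridised with input DNA on 9 tiling arrays. Per the labels, 3 strains were used with 3 biological replicates each: the wild type BY4741, a strain without NHP6A and NHP6B, and a strain without HMO1. The labels give the hmo1 knockout the same strain collection as the wild type and the nhp6ab double knockout a different origin. Cells grew in rich glucose medium and were crosslinked, and the DNA was amplified by in vitro transcription. Per the labels, Cy5 (red) was the Snf5 immunoprecipitate (IP) and Cy3 (green) the input on every array, so no dye swap separates dye from antibody.

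The deposited scanner files hold each spot's intensity, with the processed signals background-subtracted, detrended and dye-normalised within the array by Agilent Feature Extraction 10.5.1.1 per the file headers. They also hold a deposited log10 ratio of red over green, which was not used here except to check the dye orientation. The deposited series table holds log2 ratios that were a straight-line function of the background-subtracted ratio on every array, with slopes of 0.75 to 1.47 and medians of −0.0099 to −0.0037. The authors name R 2.12.1 for that table and do not state its steps, so the scanner signals were used and the table served as an alternative.

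Values were log2(IP / input) of the processed signals, with each array centred on its median over non-control probes and with no loess or quantile step. Of 62976 spots, 2329 were controls and 60647 were probes of 60 bases with a median spacing of 181 bases, 450 of them mitochondrial. Spots called outliers by Feature Extraction (2 to 54 per array) were left out, and the other spots entered the region means one by one. The median net input signal was 41.9 on hmo1 knockout replicate 3 and between 1700 and 6437 on the other arrays. The median net IP signal was 119 on wild-type replicate 3 and between 304 and 1014 on the others. The number of arrays limits the precision.

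Promoter regions were planned as the 500 bases upstream of each protein-coding gene. The deposited coordinates are on the sacCer1 build per the file headers, and an annotation of that build was not used here. The planned fallback was therefore used, the gene names in the array's own annotation. A block of probes named for a divergent pair of genes stood for their shared promoter, and any other gene was represented by all probes that carry its name, reading frame included. Regions needed at least 2 probes. This gave 1169 divergent regions (median 3 probes over 488 bases) and 2782 gene blocks (median 10 probes over 1747 bases). Of these 3951 regions, 3941 entered comparisons between strains after the deleted genes and the marker loci (HIS3, LEU2, MET17, URA3, TRP1, ADE2, LYS2 and CAN1) were left out. Probes whose label could not be matched to a gene (472) were left out. Alternative windows were the first 300, 500 or 1000 bases from a block's 5′ end. Reading frames were the probes of genes whose promoter is a divergent region (2712 with at least 2 probes).

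Groups were compared with limma 3.58.1 in R 4.3.3, in 1 fit over the 9 arrays with moderated variance, trend and robust options off and Benjamini-Hochberg adjustment over all regions. A promoter counted as bound at an adjusted p under 0.05 and a group mean of at least 1 on the log2 scale. The mean over the promoters bound on average of the 3 strains was compared by exact 2-sided permutation of arrays, where 3 against 3 cannot give a p below 0.1. Gene lists were tested with camera (preset correlation 0.01, and an estimated correlation beside it), adjusted over 21 lists. These were ribosomal protein genes, ribosome biogenesis, translation factors, glycolysis and fermentation, hexose transport, known SWI/SNF targets, amino acid synthesis, methionine and sulfur, the phosphate regulon, heat shock and chaperones, general stress, histone genes, mating genes, G1/S cell cycle, M/G1 and daughter-cell genes, cell wall, ergosterol synthesis, TCA cycle and respiration, the iron regulon, subtelomeric families (PAU and COS genes, whose members share probe sequences), and meiosis and sporulation. A divergent region counts for a list when either of its genes is a member.

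Named promoters were fixed by rule. They are the 8 largest falls and rises past the threshold in each knockout whose 3 arrays all lie on one side of the wild type's (fewer if fewer pass), the 5 largest each way between the knockouts, up to 2 members each way per list described (or the 2 largest changes as values), and the 10 highest bound promoters of the wild type. The deleted genes, the marker loci and 14 known SWI/SNF targets were always named. Of the list members named by this rule, 1 is not reported here. Groups, tests, lists and this rule were set before the data were examined.

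Input DNA at deleted genes and marker loci was averaged over all probes of the gene's own label. Missing DNA was defined, after the data were seen, as runs of at least 2 neighbouring probes whose input was at least 8-fold lower in some strains than in the others. Scan times in the file headers split the arrays into 3 scan sessions. Session 1 held wild-type replicates 2 and 3 and nhp6ab replicates 1 and 2, session 3 held wild-type replicate 1 and nhp6ab replicate 3, and session 2 held the hmo1 knockout alone. Session and strain therefore cannot be told apart for the hmo1 knockout.

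The steps were tested on simulated data with the spread of these arrays. Of 100 promoters given a 2-fold change, 94 to 98 were recovered in the 3 comparisons, and of 100 given a 4-fold change, 99 or 100, with 4 to 13 false calls. The changed promoters were drawn at random from all regions with independent normal noise, so these shares need not hold at bound promoters. There EGD2-MDM31, at −1.00 in the nhp6ab knockout against the wild type, had a limma adjusted p of 0.320 over all promoters. Alternatives covered signal type, centring, scaling, windows, probe minimums, blocks by replicate number or scan session, array weights and each array left out in turn. Tables and figures used Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.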

Results

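Snf5 occupancy was measured on 9 whole-genome tiling arrays, 3 each for wild-type yeast, a strain without NHP6A and NHP6B, and a strain without HMO1. NHP6A, NHP6B and HMO1 encode HMG-box proteins that bind and bend DNA, and the comparisons ask where Snf5 lies without them. Values are log2(Snf5 IP / input) with SD over 3 arrays unless said otherwise, and positions are on the sacCer1 build. Replicates of one strain correlated across probes at a median Pearson r of 0.658 (0.331 to 0.849), against 0.663 (0.140 to 0.778) for arrays of different strains, and probes are not independent replicates. Without hmo1 knockout replicate 3, whose input was dim, the medians were 0.712 and 0.673.

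The deleted genes were low in the input DNA of their own strain. Input over NHP6A (chromosome 16, 665570 to 665869) was −7.16 in the nhp6ab knockout relative to the 6 other arrays. Over HMO1 (chromosome 4, 812168 to 813035) it was −2.55 in the hmo1 knockout, and over NHP6B (chromosome 2, 426119 to 426994) −1.45 in the nhp6ab knockout. Each difference had an exact 2-sided permutation p of 0.0119, the smallest that 3 against 6 arrays can give. For NHP6B only 1 of 6 probes was low, and the IP channel differed by −0.34 (exact p = 0.143). The strains also differed at nutritional marker genes that laboratory strains often lack. URA3, of uracil synthesis, had an input of −8.10 ± 0.36 in the wild type, 0.66 ± 0.26 in the nhp6ab knockout and −5.82 ± 2.39 in the hmo1 knockout. MET17, of methionine synthesis, stood at −6.52 ± 0.25, 0.50 ± 0.07 and −4.46 ± 1.58 in the same order. LEU2, of leucine synthesis, stood at −8.54 ± 0.51, −2.19 ± 0.25 and −4.60 ± 2.26, and HIS3, of histidine synthesis, at −2.89 ± 0.10, −1.38 ± 0.30 and −2.15 ± 0.87. At URA3 5 of 6 probes were low in both the wild type and the hmo1 knockout. At MET17 11 of 15 probes were low in the wild type and 10 in the hmo1 knockout, and at LEU2 8 and 5 of 8. The input of hmo1 replicate 3 was dim (median net signal 41.9), which may limit how low its values can go. The gaps between these strains at URA3, MET17 and LEU2 are therefore not shown to be strain differences. TRP1, of tryptophan synthesis, was low in the nhp6ab knockout alone, at −6.14 ± 0.60 against −0.30 ± 0.06 in the wild type. ADE2, LYS2 and CAN1 lay between −0.24 and 0.16 in every strain. The nhp6ab knockout thus differed from the wild type at more loci than the deleted genes, which applies to each comparison with it.

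**Figure D1:**
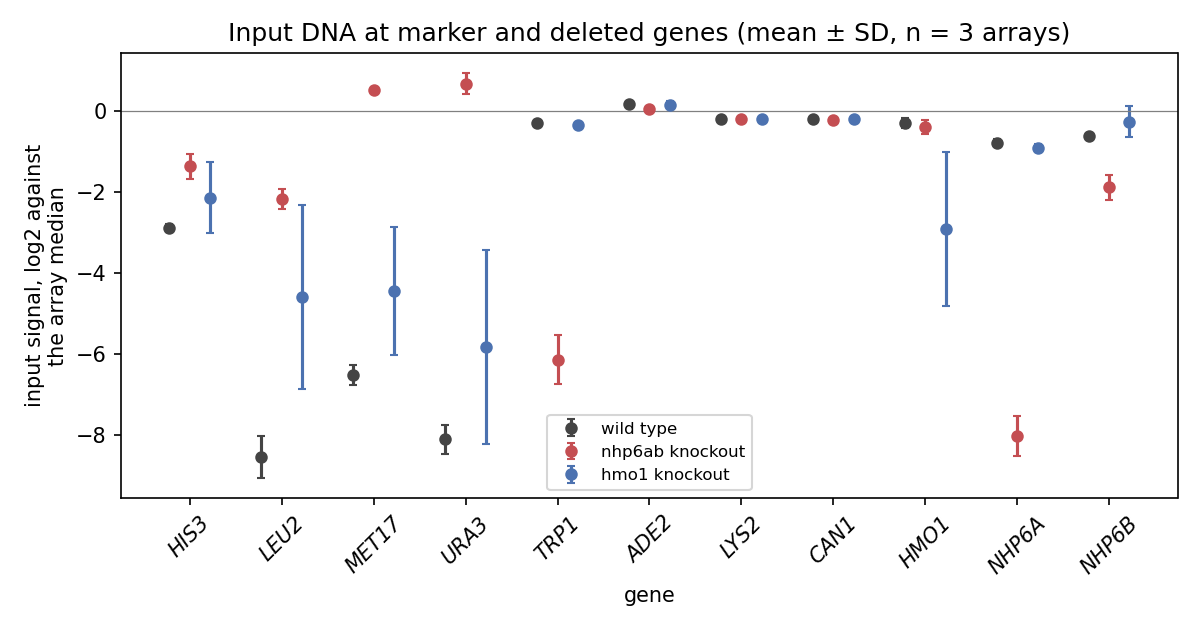
Input signal, log2 against the array median (vertical axis), at marker and deleted genes (horizontal axis), with a point at the mean of each strain and bars of 1 SD over 3 arrays. URA3 stands at −8.10 in the wild type and 0.66 in the nhp6ab knockout, and TRP1 at −0.30 and −6.14.

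In wild-type cells Snf5 was bound at 75 of 3951 promoter regions. Of the divergent promoters 3.93% were bound (46), and of the gene blocks 1.04% (29). Divergent regions hold a median of 3 probes and gene blocks 10, so these shares do not by themselves show a preference for promoters. Over 2248 pairs, wild-type divergent promoters averaged 0.015 (SD 0.50 across regions) and the paired reading frames 0.077 (SD 0.34). Between FRT1 and MYO2, a class V myosin gene, the ratio was 2.43 ± 0.03 (chromosome 15, 925073 to 925601). Between MIN4 and YAP1, an oxidative-stress transcription factor gene, it was 2.22 ± 0.14 (chromosome 13, 253308 to 253850). HSL7-CKS1, next to the gene of a Cdk-associated subunit, had 2.20 ± 0.14 (chromosome 2, 504372 to 504753). EGD2-MDM31, between a gene of the nascent-polypeptide-associated complex and a mitochondrial membrane gene, had 2.04 ± 0.26 (chromosome 8, 488370 to 488594). YDR415C-SYF1, beside a splicing gene, had 2.34 ± 0.66, and YER079W had 2.27 ± 0.68, but with loess they stood at 0.13 and 0.14. The other 4 of the 10 highest had low input signal. LEU2 (3.84 ± 1.83), URA3 (3.73 ± 0.80) and MET17 (2.43 ± 1.14) are marker genes with almost no input DNA in this strain, and at SRD1, a gene of ribosomal RNA processing (2.66 ± 0.62), the IP signal was −3.51 and the input −6.22. Of the 75 regions, 67 had an IP signal above the array median and 46 fell below the minimum of 1 without their highest probe.

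By the same criteria 36 regions were bound in the nhp6ab knockout and 37 in the hmo1 knockout. In the IP channel alone 104 regions passed in the wild type, 101 in the nhp6ab and 87 in the hmo1 knockout. These are regions bright against the array median, which is not enrichment over input. With the IP over the mean input of 8 arrays the counts were 65, 45 and 69, so the order of the strains depends on the input used. Of the 36 and the 37, 30 and 32 were also bound in the wild type (0.683 and 0.702 by chance), and 18 were bound in all 3 strains. The chance counts take the calls of the strains as independent. The same probes can respond alike on every array, so the excess does not by itself show shared binding. A region bound in one strain and not in another is not shown to differ between them. Divergent promoters made up 22 of the 36 and 33 of the 37.

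None of the known SWI/SNF targets was bound in rich glucose medium. The 13 regions averaged −0.12 ± 0.05 in the wild type, −0.18 ± 0.08 in the nhp6ab knockout and −0.14 ± 0.09 in the hmo1 knockout. In the wild type they ran from −0.61 at GAL10-GAL1, the galactose genes, to 0.19 at PHO84-GTR1, beside a phosphate transporter gene. SUC2, the invertase gene, had −0.10 ± 0.21, HO, the mating-type switching endonuclease gene, −0.05 ± 0.24, PHO5, the acid phosphatase gene, 0.08 ± 0.19, and INO1, of inositol synthesis, −0.15 ± 0.34. ADH2-UBP15, beside an alcohol dehydrogenase gene, had −0.08 ± 0.38, SER3, of serine synthesis, −0.26 ± 0.10, RNR3, of nucleotide reduction, −0.18 ± 0.07, and CHA1-VAC17, beside a serine deaminase gene, 0.12 ± 0.21. PHO8, the alkaline phosphatase gene, had 0.03 ± 0.31, HTB1-HTA1 −0.19 ± 0.19 and FLO1, a flocculation gene, −0.33 ± 0.29. FLO11 had no region. HO, PHO8, INO1, SER3, RNR3 and FLO1 were gene blocks of 11 to 18 probes with the reading frame included. Averaging over such a block would lower a narrow promoter signal, so binding at these promoters is not excluded. Snf5 was low over the ribosomal protein genes in every strain, at −0.15 in the wild type, −0.33 in the nhp6ab knockout and −0.21 in the hmo1 knockout (camera adjusted p = 0.000390, 1.8e-10 and 7.5e-06). In the same order the adjusted p was 0.745, 0.669 and 0.584 with an estimated correlation. Glycolysis and fermentation genes were also low in the wild type, at −0.27 (adjusted p = 0.00784), as were amino acid synthesis genes, at −0.14 (adjusted p = 0.0359). For both of these lists the adjusted p was 0.745 with an estimated correlation.

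Without NHP6A and NHP6B, Snf5 fell at 7 of the 45 promoters bound on average of the 3 strains, when those 45 were tested by themselves. The largest fall was between YLR225C and BUR2, a cyclin gene of transcription elongation (chromosome 12, 588951 to 589202), from 1.62 ± 0.22 to 0.59 ± 0.10 (change −1.03, SE 0.15, limma adjusted p = 0.000929). EGD2-MDM31 fell by 1.00 on the log2 scale, from 2.04 ± 0.26 to 1.03 ± 0.40 (SE 0.24, adjusted p = 0.0164). EAR1-HOT1, next to the gene of an osmostress transcription factor (chromosome 13, 605536 to 605844), fell from 1.25 ± 0.33 to 0.50 ± 0.05 (adjusted p = 0.0101). MIN4-YAP1 changed by −0.60 (adjusted p = 0.0427), and TUP1-CSM1, upstream of the corepressor gene TUP1 (chromosome 3, 262512 to 263314), by −0.54 (adjusted p = 0.0427). MDM34-KIP3, between a gene of the contacts of endoplasmic reticulum and mitochondria and a kinesin gene (chromosome 7, 84232 to 84899), changed by −0.53 (adjusted p = 0.0452). MYO4-FRT2, beside a class V myosin gene (chromosome 1, 92435 to 92914), changed by −0.50 (adjusted p = 0.0427). All 7 were lower in the IP channel too and in both scan sessions that held the 2 strains. The IP is part of the ratio and the sessions split the same arrays, so neither is separate support. At YLR225C-BUR2 the IP channel changed by −1.56 and the ratio by −1.03, so the input was lower too. Whether the DNA differs there was not tested. EGD2-MDM31 and EAR1-HOT1 rest on 2 probes each. The 7 names were chosen after their values were seen.

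In the main fit none of these falls passed the test over all promoters. Of 3941 promoters limma called 0 lower and 2 higher, with 261 lower and 71 higher at an unadjusted p under 0.05 (197 in all by chance). YLR225C-BUR2 did pass with array weights (−0.97, limma adjusted p = 0.00848) and in the IP channel alone (−1.56, limma adjusted p = 0.0124). In 17.3% of the promoters the 3 arrays of one strain lay clear of the other's, where chance gives 10%. Over the 45 bound promoters the mean was 1.62 ± 0.23 in the wild type and 1.24 ± 0.22 in the nhp6ab knockout, with 43 of the 45 changes below 0. The difference of −0.38 had an exact p of 0.1, the smallest that 3 against 3 can give, and was −0.51 within scan session 1 and −0.12 within session 3 (1 array each). It was −0.10 with each array divided by its spread and −0.025 with quantile scaling (exact p = 0.5 and 0.8). Without nhp6ab replicate 1 or wild-type replicate 3 it was −0.25 (exact p = 0.3 each). The 45 include HXT7, and with probes of missing DNA left out the difference was −0.44. The 7 falls among bound promoters became 1 with each array divided by its spread and 0 with quantile scaling or the series table, while 1 promoter, HXT7, was called higher with each of these. Of the 7, 3 were called without wild-type replicate 1, nhp6ab replicate 1, nhp6ab replicate 2 or hmo1 replicate 2, 4 without wild-type replicate 3, and 2 without wild-type replicate 2, where 2 other promoters were called. Without hmo1 replicate 3 there were 13 falls, the 7 among them, and YLR225C-BUR2 and EAR1-HOT1 were called with any single array left out.

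**Figure D2:**
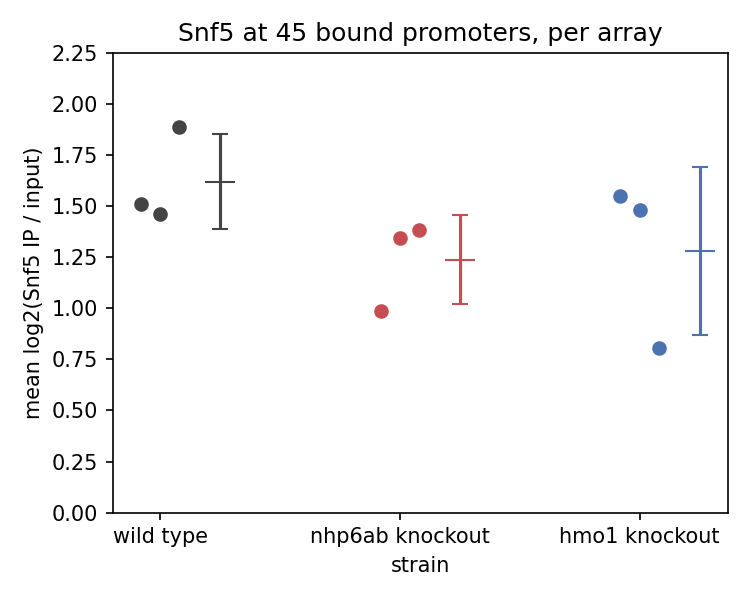
Mean log2(Snf5 IP / input) over the 45 promoters bound on average (vertical axis) by strain (horizontal axis), with a point per array and, beside the points, the mean with bars of 1 SD. Wild-type arrays lie at 1.46 to 1.89, nhp6ab arrays at 0.99 to 1.38 and hmo1 arrays at 0.81 to 1.55.

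**Figure D3:**
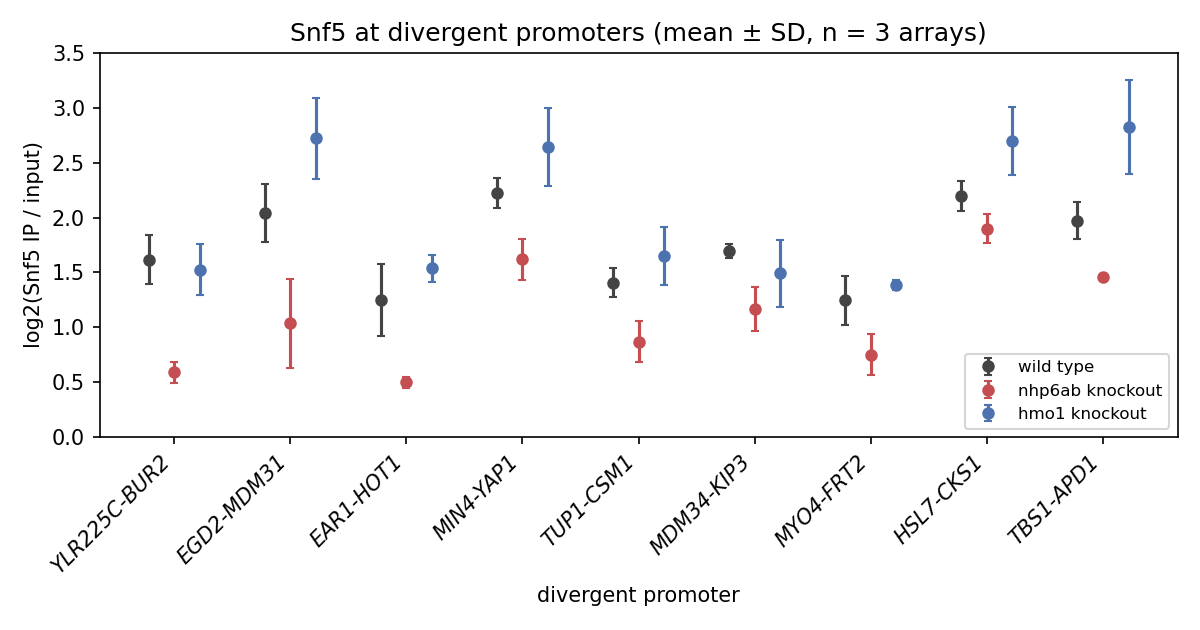
Log2(Snf5 IP / input) (vertical axis) at the 7 promoters that fell in the nhp6ab knockout among those bound on average, and at HSL7-CKS1 and TBS1-APD1 (horizontal axis), with a point at each strain's mean and bars of 1 SD over 3 arrays. YLR225C-BUR2 stands at 1.62 in the wild type and 0.59 in the nhp6ab knockout, and TBS1-APD1 at 2.83 in the hmo1 knockout.

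The ratio over HXT7 and HXT6, neighbouring and near-identical hexose transporter genes, rose in the nhp6ab knockout while both of its channels were far lower. HXT7 (chromosome 4, 1155961 to 1157806) went from 0.39 ± 0.12 to 2.67 ± 0.51 (change 2.28, SE 0.22, limma adjusted p = 0.00234), and HXT6 (1157905 to 1162940) from 0.12 ± 0.06 to 1.90 ± 0.43 (change 1.78, SE 0.19, adjusted p = 0.00346). The input over HXT7 differed by −6.91 and the IP by −4.63, and over HXT6 by −5.20 and −3.40. Over 16 neighbouring probes (1156116 to 1159553) the median input difference was −7.72, so the ratio compares residual signals. With normexp background, which damps low signals, the changes were −0.67 and −0.35. The change was 2.03 and 1.79 within scan session 1 and 2.78 and 1.77 within session 3. The limma adjusted p was 0.185 and 0.207 with session as a fixed block, and 0.00281 and 0.00381 with session as a random block. Without HXT6 and HXT7 the 16 other hexose transport regions averaged −0.0061, with 7 below 0.

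**Figure D4:**
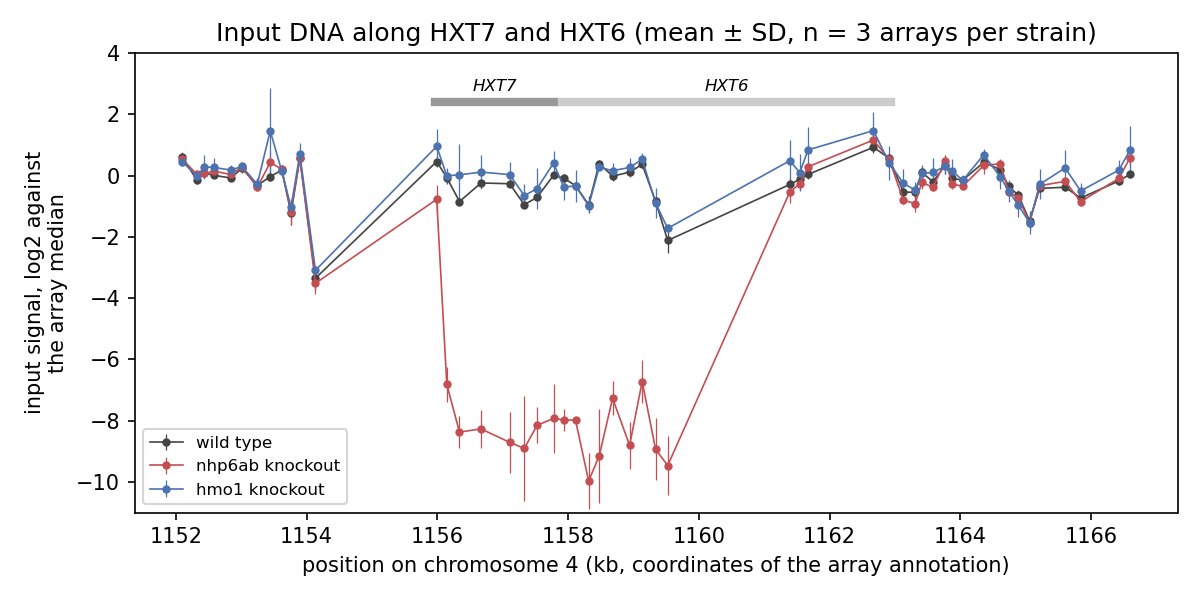
Input signal, log2 against the array median (vertical axis), along chromosome 4 (horizontal axis, kb in sacCer1), with a point per probe at each strain's mean, bars of 1 SD over 3 arrays and grey bars over the HXT7 and HXT6 blocks. From 1156116 to 1159553 the 16 probes of the nhp6ab knockout average −8.30, against −0.33 in the other strains.

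Snf5 over ribosomal protein genes was lower in the nhp6ab knockout than in the wild type. Their 131 regions averaged −0.33 ± 0.04 against −0.15 ± 0.13 (change −0.18), with 108 of the changes below 0 (camera adjusted p = 0.000951; adjusted p = 0.777 with an estimated correlation). Of the members 0 passed limma over all promoters, and 1 passed adjusted over the list alone, RPP1A, a ribosomal stalk protein gene (−0.71, SE 0.13, adjusted p = 0.0249). RPS22A-RPL39 had a change of −0.73. The list had an adjusted p of 0.00205 with scan session as a block and 0.000735 in session 1 alone, with mean changes of −0.22 in session 1 and −0.11 in session 3. It was no longer called without wild-type replicate 3 (adjusted p = 0.170), with the first 300 bases (0.0928) or 500 bases, with the highest probe of each region, or in divergent regions only, where its change relative to all other promoters was −0.084 (exact p = 0.4), against −0.112 in gene blocks only and −0.117 in both (exact p = 0.1 each). Over 18 settings its adjusted p ran from 7.15e-07 to 0.174 and its mean from −0.23 to −0.11. These do not include the first 500 bases, the highest probe or divergent regions only. Hexose transport was called upward (mean 0.22, median 0.04, adjusted p = 0.0235; adjusted p = 0.777 with an estimated correlation), with HXT6 and HXT7 past the threshold over all promoters. Adjusted over the list alone 3 passed, the third being SCM3-RGT2, beside a glucose sensor gene, at −0.45. The list had an adjusted p of 0.0662 with scan session as a block and 0.353 in session 1 alone.

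**Figure D5:**
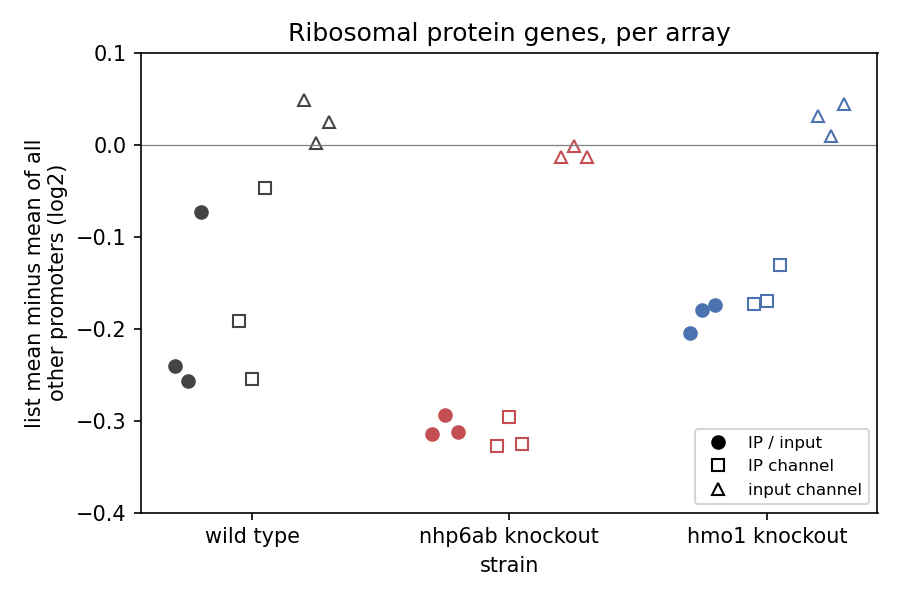
Mean of the ribosomal protein genes minus the mean of all other promoters (log2, vertical axis) by strain (horizontal axis), a symbol per array, with filled circles for IP / input, squares for the IP channel and triangles for the input channel. In IP / input wild-type replicate 3 stands at −0.07, the other wild-type arrays at −0.24 and −0.26, and the nhp6ab arrays at −0.31, −0.29 and −0.31.

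The other 19 lists were not called in the nhp6ab knockout (adjusted p 0.0882 to 0.990), and their mean changes ran from −0.23 to 0.02. Histone genes had the lowest mean, −0.23 over 6 regions. HTB1-HTA1, a divergent pair of histone genes, passed adjusted over the list alone (−0.61, SE 0.16, adjusted p = 0.0158), as it did among the known SWI/SNF targets (mean −0.06, adjusted p = 0.0342). Meiosis and sporulation genes averaged −0.16, with SPO16-RTT107 at −0.75 and SPO22-HOP1 at −0.69 passing adjusted over the list alone. Both pairs hold a gene of meiotic chromosome pairing. Among G1/S genes (mean −0.04) RFA1-SEN34, beside a replication protein gene, passed alone at −0.67. The iron regulon averaged −0.02, with FIT1-STL1, beside a cell wall gene of iron retention, at −0.53 and ENB1, a siderophore transporter gene, at 0.47, both passing over the list alone. Translation factors averaged −0.15 (RRP14-TEF4 −0.73), ribosome biogenesis −0.08 (RLP7-DOM34 −0.71), cell wall genes −0.09 (CDC34-PST1 −0.58) and ergosterol synthesis −0.08 (COQ2-MVD1 −0.63). Mating genes averaged −0.07 (GYP8-STE2 0.58), subtelomeric families −0.07 (PAU12 −0.41), the phosphate regulon −0.06 (ARB1-PHM8 −0.72), and heat shock and chaperones −0.05 (YDJ1-MTQ1 −0.50). TCA cycle and respiration averaged −0.04 (COX12 0.45), general stress −0.03 (COQ6-GND2 −0.46), and M/G1 and daughter-cell genes −0.03 (SWI5-EKI1 −0.39). Amino acid synthesis averaged 0.02, glycolysis and fermentation 0.02 (PGI1 0.40), and methionine and sulfur 0.01 (MET6-IES5 −0.43). Mean and camera direction differed in sign in 9 of the 21 lists, and mean and median in 2, and the median promoter changed by −0.06.

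Without HMO1, limma called 0 of 3941 promoters lower and 0 higher (smallest adjusted p 0.169), with 332 lower and 94 higher at an unadjusted p under 0.05. Over the 45 bound promoters the mean was 1.28 ± 0.41 against 1.62 ± 0.23 in the wild type, a difference of −0.34 (exact p = 0.5), which was −0.11 without hmo1 replicate 3 and 0.06 without wild-type replicate 3 as well. Tested by themselves, 3 of the 45 rose and 11 fell. TBS1-APD1 (chromosome 2, 544549 to 544937) rose from 1.97 ± 0.17 to 2.83 ± 0.43 (adjusted p = 0.0338), EGD2-MDM31 by 0.68 (adjusted p = 0.0494) and HSL7-CKS1 by 0.50 (adjusted p = 0.0423), and their IP channels changed by 0.76, 0.75 and 0.53. The 11 falls included SRD1 (−2.17), SAD1-YFR006W beside a splicing gene (−1.47), MLP2-RPL40A beside a ribosomal fusion gene (−1.09), GOT1 of vesicle transport (−1.01), VMA9 of the vacuolar ATPase (−0.99) and EDC1 of mRNA decapping (−0.83). The others were YER079W (−1.14), YHR086W-A (−0.91), NIT3-LUG1 (−0.89), the splicing gene CWC25 (−0.80) and MAM3-GPD2 beside a glycerol synthesis gene (−0.58). In the IP channel these 11 differed by −0.51 to −0.03. Without hmo1 replicate 3 SRD1 changed by −1.23 and SAD1-YFR006W by −0.89, and without wild-type replicate 3 NIT3-LUG1 changed by −0.56. At SRD1 the IP channel differed by −0.32 and both channels were low in the wild type, so its ratio compares residual signals. These names too were chosen after their values were seen.

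With an array left out, the falls among bound promoters in the hmo1 knockout numbered 10 or 11 in 5 of 9 cases. Falls and rises were 2 and 7 without hmo1 replicate 3, and 0 and 0 without wild-type replicate 1 or wild-type replicate 3. They were 1 and 1 without nhp6ab replicate 3, which leaves these changes as they are and alters the shared estimate of the spread. TBS1-APD1 was called higher in each of these cases except without wild-type replicate 1 or wild-type replicate 3. Falls and rises were 0 and 6 in the IP channel alone, 0 and 0 with each array divided by its spread, 3 and 17 with quantile scaling and 1 and 5 with loess. The hmo1 arrays form a scan session of their own. None of the 21 lists was called in the hmo1 knockout (adjusted p 0.500 to 0.982), with mean changes of −0.16 to 0.03, mean and camera direction of opposite sign in 8 lists and mean and median in 4. The lowest adjusted p was 0.987 with an estimated correlation. Ribosomal protein genes, many of whose promoters Hmo1 is known to bind, averaged a change of −0.06 with 70 of 131 below 0 (adjusted p = 0.867), and MLP2-RPL40A at −1.09 and SEC10-RPS31 at −0.82 were its largest changes. Translation factors had the lowest mean, −0.16, and 2 regions passed adjusted over the list alone: DIG1-CAM1, beside an elongation factor gene, at −0.94 (adjusted p = 0.00351) and ATO3-EFT2, beside another, at −0.62 (adjusted p = 0.0156).

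Between the knockouts, Snf5 was lower in the nhp6ab than in the hmo1 knockout at 3 divergent promoters, and the ratio was higher at HXT7 and HXT6. EGD2-MDM31 stood at 1.03 ± 0.40 against 2.72 ± 0.37 (difference −1.69, limma adjusted p = 0.0222), and TBS1-APD1 at 1.46 ± 0.01 against 2.83 ± 0.43 (−1.37, adjusted p = 0.0222). EAR1-HOT1 stood at 0.50 ± 0.05 against 1.54 ± 0.12 (−1.04, adjusted p = 0.0371). EGD2-MDM31 and EAR1-HOT1 rest on 2 probes each and TBS1-APD1 on 3, so a response of single probes is not excluded. HXT7 (2.68, adjusted p = 0.000473) and HXT6 (1.85, adjusted p = 0.00241) carry the DNA difference given above, and their IP channels differed by −4.60 and −3.51. Among the 45 bound promoters tested by themselves 10 were lower, including HSL7-CKS1, MIN4-YAP1, TUP1-CSM1 and YLR225C-BUR2. All 10 were lower in the IP channel too, which is part of the ratio. At YLR225C-BUR2 the IP channel differed by −1.60 and the ratio by −0.94, so here too the input was lower. At an unadjusted p under 0.05, 216 promoters were lower and 155 higher. The mean over the 45 bound promoters, HXT7 among them, differed by −0.04 (exact p = 0.9), and by −0.10 with probes of missing DNA left out (exact p = 0.6). Ribosomal protein genes were lower (−0.12, camera adjusted p = 0.000468), meiosis and sporulation genes were lower (−0.13, adjusted p = 0.0383) and hexose transport was higher (0.33, adjusted p = 0.00345), with a lowest adjusted p of 0.744 with an estimated correlation. Without HXT6 and HXT7 the 16 other hexose transport regions averaged a difference of 0.09. The 3 lower calls became 0 without nhp6ab replicate 1, nhp6ab replicate 2 or hmo1 replicate 2, 1 without nhp6ab replicate 3 or hmo1 replicate 1, and 8 without hmo1 replicate 3, and no scan session held both knockouts.

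The changes of the 2 knockouts against the same wild-type arrays correlated across promoters at 0.469, within the 0.458 to 0.535 simulated for unchanged groups against shared controls. Their covariance was 0.0246, above the 0.0131 to 0.0168 simulated. At an unadjusted p under 0.05, 74 promoters were lower in both knockouts, out of 261 and 332, where the simulated groups gave 22.3 out of 97.5 and 98.4, so the lists differ in size. In both knockouts 12 were higher (21.7 simulated). With each array left out in turn the correlation had a jackknife SE of 0.231, wider than the simulated range. None of these comparisons therefore shows a shared response of the 2 knockouts or excludes it. Over reading frames limma called 0 of 2707 in each of the 3 comparisons, with 180, 232 and 231 at an unadjusted p under 0.05. Snf5 was bound over 43 frames in the wild type (1.59%), 29 in the nhp6ab knockout and 7 in the hmo1 knockout.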

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

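The tests of the HXT6 and HXT7 region, of array scale and of the input channel for ribosomal protein genes, and of missing wild-type DNA were chosen only after the results were seen.

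The change against the wild type differed between the 2 knockouts at 5 promoters by limma's test of the difference itself, which drew attention to EGD2-MDM31, TBS1-APD1 and EAR1-HOT1 (lower in the nhp6ab knockout) and HXT7 and HXT6 (higher ratio). The highest count in another split of those 6 arrays was 0, and 1 of the 10 splits, the real one, gave 5. The 10 splits are too few for a share under 0.05. The input channel, which the comparisons of Snf5 do not report by itself, showed DNA that was low in the nhp6ab knockout away from the deleted genes. The median input difference from the other strains was −8.07 over 5 probes at IPP1 and YBR013C (chromosome 2, 259035 to 266111), −7.72 over 16 probes at HXT7 and HXT6, and −3.51 over 2 probes at RPL26A (chromosome 12, 817835 to 818063).

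The first pattern is the higher Snf5 ratio at HXT6 and HXT7 in the nhp6ab knockout. More Snf5 at the locus would raise the IP signal, but the IP channel differed by −3.85 over the probes of both regions. DNA missing from this strain would lower the input, and the median input difference was −7.48. A missing stretch may therefore account for the ratio, which then compares 2 residual signals. Whether the loss came with the strain's origin or later was not tested, and the strain's background differs from the wild type's by the labels.

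The second pattern is the lower Snf5 over ribosomal protein genes in the nhp6ab knockout, a change of −0.117 relative to all other promoters (exact p = 0.1, the smallest possible; the list's camera call is lost at adjusted p = 0.777 with an estimated correlation). A difference in array scale alone would vanish when each array is divided by its spread, and the change was then −0.152. Division by the spread does not undo a weak signal from a dim IP, so IP yield was not tested. A GC trend or a difference in the input would vanish with GC content taken out (−0.115) or in the IP channel alone (−0.152). The change was −0.084 in divergent regions only (exact p = 0.4) and −0.112 in gene blocks only (exact p = 0.1). What stays open is the strain background, the IP yield and, against the wild type, the single array behind the call. Wild-type replicate 3 stood at −0.07, and without it the list had a camera adjusted p of 0.170. The list's own mean change then went from −0.18 to −0.11. The hmo1 arrays stood at −0.20, −0.18 and −0.17, above the nhp6ab arrays at −0.31, −0.29 and −0.31. Between the knockouts the list was called lower in 17 of 18 settings, but no scan session held both. With an estimated correlation the lowest adjusted p of any list there was 0.744. Loss of Nhp6 could lower Snf5 over these genes, as a hypothesis found and tested on the same data.

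The third pattern is the 75 promoters bound in the wild type. DNA missing from the wild type would raise ratios as at LEU2, and probes of missing DNA lay in 4% of the bound promoters. That rule cannot count DNA with low input in every strain. Of the 75 regions, 9 had an input below −1, SRD1 at −6.22 among them, so the 4% does not settle how many ratios come from low input. Response of single probes would leave their neighbours near 0, and neighbours within 250 bases of the 849 probes at or above 2 averaged 0.51, against 2.95 for the probes. That value lies between the 2 outcomes, so single-probe response and narrow Snf5 sites cannot be told apart at a spacing of 181 bases.

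The same 10 splits of 3 against 3 were counted for the other model results, and they are too few for a share under 0.05 in each case. For the nhp6ab knockout against the wild type, promoters past the threshold were 2 with at most 0 in another split (1 split as large), lists 2 with at most 1 (1 split as large) and reading frames 0 with at most 0 (10 splits as large). For the hmo1 knockout against the wild type, promoters were 0 with at most 0, lists 0 with at most 2 and reading frames 0 with at most 1 (10 splits as large in each).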

How the results depend on the processing

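The alternatives chosen only after the data were seen were the IP channel alone, the IP over the mean input of 8 arrays, probes of missing DNA left out, divergent regions only, the first 500 bases, scan session as a random block, session 1 alone, both dim arrays left out, and the test of bound promoters under other settings. The planned feature classes were not run, since the array's labels hold protein-coding names only, nor was a slide block, since the headers give 1 slide number. The cause was not tested for any change given here unless a clause states it. Dim signal limits 2 arrays, the input of hmo1 replicate 3 and the IP of wild-type replicate 3. The mean change at bound promoters in the nhp6ab knockout stayed below 0 under every alternative, from −0.51 to −0.025, and centring on the mode moved the median promoter to −0.106 and −0.105 in the 2 knockouts.

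Each array left out in turn gave 1 to 2 lists in the nhp6ab knockout (1 without wild-type replicate 1 or 2), 0 to 1 in the hmo1 knockout (1 without wild-type replicate 3), 0 to 8 promoters lower between the knockouts, and −0.26 to 0.12 for the knockouts' difference in mean change.

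With normexp background, which adds an offset of 50 to both channels, HXT7 and HXT6 changed by −0.67 and −0.35 against the wild type and by −0.30 and −0.23 against the hmo1 knockout. Then 0 promoters were higher and 1 list was called against the wild type, 1 promoter was lower in the hmo1 knockout, and 0 were lower and 0 higher between the knockouts. Among the 45 bound promoters tested by themselves, 13 were still lower between the knockouts, EGD2-MDM31, TBS1-APD1 and EAR1-HOT1 among them. The wild-type levels of LEU2, URA3 and MET17 became −0.098, −0.14 and −0.088.

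With the deposited log2 ratios as values, 57 promoters were bound in the nhp6ab knockout (68 in the wild type), 0 were higher and 1 list called against the wild type, 1 was higher between the knockouts, and the hmo1 mean change was 0.052. With loess 27, 14 and 22 promoters were bound in the wild type, nhp6ab and hmo1 knockout, 0 were higher in the nhp6ab knockout, 1 was lower in the hmo1 knockout, and its mean change was 0.044. With quantile scaling the hmo1 knockout had 3 promoters higher and a mean change of 0.26, and 6 were lower between the knockouts. With each array divided by its spread the hmo1 mean change was 0.024. With the mode as centre the knockouts differed by 0.0026.

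With only probes well above background in the input of all arrays, 0 promoters were higher and 1 list called in the nhp6ab knockout, HXT6 changed by −0.14 and HXT7 by 0.91 (1.51 against the hmo1 knockout, past the threshold in neither), and 0 were lower and 0 higher between the knockouts. With probes of missing DNA left out 0 were higher and 1 list called, HXT6 changed by −0.14, 0 were higher between the knockouts, and MET17 stood at −0.37 in the wild type.

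In the IP channel alone 104 promoters passed the minimum in the wild type, 101 in the nhp6ab and 87 in the hmo1 knockout, a measure of IP signal and not of enrichment over input. Against the wild type the nhp6ab knockout had 9 lower, 0 higher, 1 list and 1 reading frame lower, with HXT7 at −4.63 and HXT6 at −3.40, and the hmo1 knockout had 1 list. Between the knockouts 32 were lower, with HXT7 at −4.60 and HXT6 at −3.51. Both counts of lower promoters include HXT6, HXT7, YBR013C and RPL26A, where input DNA was low in the nhp6ab knockout. Others also fell in the IP channel without a fall in the ratio. POP8 had −0.82 and −0.003 against the wild type, and RPS28B −1.53 and 0.40 between the knockouts. Some fell in both, such as EGD2-MDM31 between the knockouts (−1.62 and −1.69). The counts are therefore not counts of Snf5 loss. Wild-type LEU2, URA3, SRD1 and MET17 stood at −4.66, −4.33, −3.51 and −4.05. With the IP over the mean input of 8 arrays 69 promoters were bound in the hmo1 knockout, which had 1 list and a mean change of 0.14. The nhp6ab knockout had 7 lower, 0 higher, 1 list and 1 reading frame lower, with HXT7 at −4.62 and HXT6 at −3.40. Between the knockouts 32 were lower, with HXT7 at −4.61 and HXT6 at −3.52, and wild-type MET17 stood at −0.51.

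With the first 1000 bases 1 promoter was higher and 1 list called in the nhp6ab knockout, HXT6 changed by −0.014, and 1 was higher between the knockouts. With the first 300 bases 192, 87 and 63 promoters were bound, 0 lists were called, HXT6 changed by −0.014, the knockouts differed by 0.15 and MET17 stood at −0.41. With the first 500 bases 130 and 63 were bound in the wild type and nhp6ab knockout, 0 lists were called, HXT6 changed by −0.014, 1 was higher between the knockouts, which differed by 0.067, and MET17 stood at −0.54. HXT6 loses its low probes in these windows.

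With the highest probe of each region 1455, 1002 and 616 promoters passed the criteria for binding. The highest probe lies at or above its region's mean by selection alone, so these counts do not show more binding. With this setting 1 promoter was higher and 0 lists called in the nhp6ab knockout. Between the knockouts 0 were lower and 1 higher, with a difference of 0.45. With a minimum of 1 probe 55 were bound in the nhp6ab knockout, 1 reading frame was lower, and the knockouts differed by 0.12. With divergent regions only, which leaves out HXT6 and HXT7, 46 and 22 were bound in the wild type and nhp6ab knockout, 0 were higher and 0 lists called in the nhp6ab knockout, 1 was lower in the hmo1 knockout and 0 were higher between the knockouts. At a 1.5-fold minimum 269, 155 and 80 were bound. With the 500 highest promoters the knockouts differed by 0.11.

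The replicate numbers did not pair the arrays (0 of 9 pairs of residuals above 0.1), and a replicate block gave 1 promoter lower between the knockouts. Scan session as a fixed block gave 0 higher and 1 list in the nhp6ab knockout, session 1 alone gave 0 and 1, and a random session block gave 8 lower between the knockouts. A fit of only 2 groups gave 1 lower between the knockouts. Array weights gave 1 lower in the nhp6ab knockout and 15 between the knockouts. Without wild-type replicate 3 and hmo1 replicate 3 together the hmo1 knockout had 2 lists and a mean change of 0.059, and 13 were lower between the knockouts. The estimated correlation gave 0 lists in the nhp6ab knockout. NHP6B differed by −0.34 in the IP channel.

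With only bound promoters tested, lower and higher were 7 and 1 in the nhp6ab knockout, 11 and 3 in the hmo1 knockout, and 10 and 1 between them. Array weights gave 17 falls in the nhp6ab knockout (all 7 among them), scan session as a fixed block 10 (6 of the 7), a replicate block 4 and loess 3 (all among the 7), and normexp background 2, of which 1 was among the 7 and the other was HXT7. Of reading frames, limma called 0 lower or higher under the other alternatives.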

Other observations

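Mitochondrial DNA was depleted in the Snf5 IP of every array. The median ratio of the 450 mitochondrial probes ranged from −3.68 on hmo1 replicate 1 to −1.34 on wild-type replicate 3. Wild-type replicate 3 had the dimmest IP (119), and hmo1 replicate 3, which had the dimmest input (41.9), stood at −1.73. Neighbouring probes correlated at 0.16 on wild-type replicate 3 and at up to 0.41 on nhp6ab replicate 1. The median input of each nuclear chromosome lay between −0.107 and 0.058 on every array, and that of mitochondrial probes between 0.52 and 2.03.

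YBR013C, an uncharacterised gene in the stretch of low input on chromosome 2, had a ratio of 0.96 ± 0.96 in the nhp6ab knockout and −0.61 ± 0.18 in the wild type, with an input difference of −4.59. RPL26A, a ribosomal protein gene, had an input difference of −1.09 over its whole block and an IP difference of −1.45. Both names were chosen after their values were seen.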
